A study of Mus musculus with 2 samples.

How the data were processed

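Total RNA of proliferating C2C12 myoblasts was labelled with Cy3 or Cy5 during cDNA synthesis and hybridised to 2 two-colour cDNA arrays, per the labels' protocols. The labels call the arrays biological replicates, with PRDM2sh against GFPsh RNA on each and the dyes exchanged. The label of replicate 2 names the hairpin as sh1, and that of replicate 1 gives no number. The deposited intensity of each spot is on a linear scale for each dye, per the file headers, which name the RNA and dye of each column. The scanner and the background method are not given in the sources used here. The intensities held zeros and no negative values. Of the clone spots of array 1, 1.22% in Cy3 and 20.2% in Cy5 were at 0, and on array 2 0.856% and 16.5%. The deposited log2 ratio table of the authors was used only as an alternative. Set against the intensities, its values run as PRDM2sh over GFPsh on both arrays with an intensity curve removed within blocks of 650 spots. Its medians are -0.05 and 0.03, and its exact normalization stays unknown. It is blank for 7164 spots of array 1, with 1 whole block among them, and for 5575 of array 2.

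Clone names, symbols and Entrez IDs came from the array files. Of 15247 clones 9347 had a symbol. The Entrez IDs of 9281 matched the RefSeq gene table of assembly GRCm38.p6, and 1444 clones took a newer symbol from it. No array coordinates were used.

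The design fixed before the data were examined named normexp background correction unless the intensities were already corrected. Normexp broke down on these values, so 50 was added to each channel with no further correction. Log ratios were normalized by loess within each array (span 0.3), with control spots at weight 0, and the spots of a clone were averaged. The files give no background columns, so the fixed detection rule was replaced by the 95th percentile of the 226 buffer spots. This limit was 1648 in Cy3 and 369 in Cy5 on array 1, and 937 and 305 on array 2. Clones with at least 1 channel above the limit on each array were kept, 7927 in all. A gene was its brightest clone, which gave 4171 named genes and 2706 unnamed clones. Of the clone spots, 47.1% in Cy3 and 38.4% in Cy5 were above the limit on array 1, and 77.2% and 46.0% on array 2.

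The log2 ratio of array 2 was turned, and the mean over both arrays was tested against 0 with lmFit and eBayes in limma 3.58.1 (R 4.3.3), two-sided, with Benjamini-Hochberg adjustment. This leaves 1 residual degree of freedom and 10.4 prior degrees. A dye term could not be added with 2 arrays. A dye effect of equal size on both arrays cancels in the mean and adds to the spread, and an unequal one leaves a remainder in the mean. Gene lists were tested with camera at a preset correlation of 0.01 where at least 5 members were measured, with adjustment over 14 of the 23 lists. The test was run on simulated data in which 200 genes changed by known folds, drawn from the spread of the mean with and without the observed dye component. For a clone not well above background on either array in one group, the measured log2 ratio is given with that limit and with no fold.

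The rule for naming genes was Prdm2, then in each direction the 10 genes of one sign on both arrays with the largest smaller value, up to 4 members with the smallest p from each list, and 6 genes of interest. Since no gene passed, both sets of 10 were filled from genes that did not pass. Unnamed clones were passed over. Not every list member found by the rule is printed. One gene that the rule names is not reported here. Alternatives fixed before the data were examined were another offset, leaving out spots at 0, median centring, loess within blocks, Aquantile, other filters, other treatment of several clones, a trended robust prior, separate channels, the authors' table and each array alone. Added after the data were seen were a limit from Arabidopsis spots, clone spots within 2-fold of each other, the blank block left out, array 2 not turned, and the removal of spots at 0 beside a channel above its limit. This removal was tried after the ratios of Rps25 and Rpl36 were seen to rest on such spots. It was not made the main setting, which keeps spots at 0 with the offset.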

Results

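RNA of C2C12 cells, a mouse myoblast line that can be kept dividing or led to form muscle fibres, was compared between cells carrying a short hairpin RNA against PRDM2 (PRDM2sh) and control cells with a hairpin against GFP (GFPsh). PRDM2, also called RIZ, is a zinc finger protein of the PRDM family of chromatin regulators. All cells were proliferating. Each of 2 biological replicates was hybridised to 1 two-colour array, and the dyes were exchanged between the arrays, with PRDM2sh in Cy5 on array 1 and in Cy3 on array 2. Ratios are given as PRDM2sh over GFPsh. Each array held 31200 spots, among them 15247 mouse cDNA clones spotted 2 times each. On array 1 the median spot intensity was 1580 in Cy3 and 240.4 in Cy5, and on array 2 it was 1478 in Cy3 and 262 in Cy5. The number of arrays limits the precision of every value below.

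The first question was whether the targeted transcript itself was lower in PRDM2sh cells. The brighter of the 2 Prdm2 clones gave a log2 ratio of -0.27 on array 1 and -0.47 on array 2, a mean of -0.37 ± 0.14 (SD, n = 2), or 77.3% of the GFPsh level. The other clone gave -0.24 on array 1 and 0.16 on array 2. On array 1 neither clone was above the detection limit in either channel, so Prdm2 was outside the genes tested. In a fit over all 12827 genes and clones its adjusted p was 1.000 (limma), with a 95% interval of the log2 ratio from -1.88 to 1.14. A lower Prdm2 level was not detectable at this signal and with this test, and the values check the labels only weakly. The interval rests on the spread across all genes, with a standard error of 0.62 against an SD of 0.14 for Prdm2 itself. In simulated data with the observed dye component the same kind of test recovered 0 of 50 genes changed 16-fold.

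The main comparison asked which transcripts differed in the PRDM2sh cells. Bgn, Col1a2 and H19 were among the 10 named genes with the highest ratios on both arrays. Bgn, which encodes the matrix proteoglycan biglycan, had a mean log2 ratio of 1.81 ± 0.22 (SD, n = 2), or 3.52-fold. Col1a2, a chain of type I collagen, had a mean of 1.14 ± 0.40, or 2.20-fold. H19, the imprinted non-coding RNA that is abundant in C2C12 cells, had a mean of 1.15 ± 0.51, or 2.22-fold. Igfbp5, Spp1 and Serpine2 were among the 10 with the lowest. Igfbp5, a binding protein of insulin-like growth factors, had a mean of -1.71 ± 0.05, 3.26-fold lower. Spp1, which encodes the secreted phosphoprotein osteopontin, had a mean of -1.40 ± 0.10, 2.64-fold lower. Serpine2, a secreted protease inhibitor, had a mean of -1.68 ± 0.08, with PRDM2sh above the detection limit on 1 of 2 arrays. None of these passed the test over all genes. The ranking rests on the dyes given for array 2. With that array not turned the means were 0.16 for Bgn, -0.29 for Col1a2 and -0.36 for H19, and 0.03 for Igfbp5, 0.07 for Spp1 and -0.05 for Serpine2.

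Of 6877 genes and unnamed clones tested with limma, 0 were higher and 0 lower at an adjusted p under 0.05, and the smallest adjusted p was 1.000. At an unadjusted p under 0.05 there were 23, where 344 would be met by chance. The separate-channel fit in limma also gave 0 in each direction, with 19 at an unadjusted p under 0.05. In simulated data with the observed dye component, the same test recovered 0 of 50 genes changed 16-fold, and without that component it recovered 38 of 50 genes changed 2-fold. A count of 0 here therefore says nothing on how many transcripts differed. Each simulated array was given the spread of the mean of both arrays as its noise. The simulated mean was thus less noisy than the observed one, and the 38 of 50 may be too high.

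The remaining genes of the 10 with the highest values on both arrays were measured less firmly. Sfn, a 14-3-3 protein, Ighm and Psmg1 were not well above background in GFPsh cells on either array. Their measured mean log2 ratios were 1.37 ± 0.30, 1.30 ± 0.60 and 0.98 ± 0.17, and the second, dimmer clone of Ighm had -0.18. Ighm had 1 Cy5 spot listed at 0 on each array. Over the alternatives, array 2 not turned apart, Sfn ranged from 1.37 to 2.53, Ighm from 0.88 to 2.40 and Psmg1 from 0.71 to 1.05. For Fbxw27 the brightest clone gave 1.36 ± 0.66 with GFPsh not well above background on either array. Its other clone was above the limit in GFPsh on array 1 and had a mean of -0.20. The value for Fbxw27 was -0.36 with spots at 0 in either channel left out, and 0.58 with the mean over clones. Tbc1d31 had a mean of 0.95 ± 0.19, with GFPsh above the limit on 1 of 2 arrays, and Slc6a20a had 1.80 ± 1.42 with GFPsh spots listed at 0 on both arrays, 1 in Cy3 on array 1 and 2 in Cy5 on array 2. The ribosomal protein gene Rpl36 had 4.18 on array 1 and 0.78 on array 2, and 1 of its 2 Cy3 spots on array 1 was listed at 0. Its mean turned to -0.17 with spots at 0 left out and to -0.24 in the authors' log2 ratios. In this ranking 9 unnamed or provisional clones were passed over.

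Among the 10 with the lowest values, Prdm4, another member of the PRDM family, was not well above background in PRDM2sh cells on either array. Its measured mean log2 ratio was -1.86 ± 0.14, and a second, dimmer clone had 0.42 on array 1 and -1.15 on array 2. For Eif2s3x, a translation initiation factor subunit, the kept clone gave -1.91 ± 0.64 with PRDM2sh not well above background on either array. Its other clone was above the limit in PRDM2sh on array 2 and had a mean of -0.14. Cdk8, a kinase of the Mediator complex, had a mean log2 ratio of -1.32 ± 0.39. The chemokine receptor gene Ackr3 had -1.28 ± 0.31, Rbm15b had -1.56 ± 0.39, Blnk had -1.42 ± 0.62 and Rnf44 had -1.09 ± 0.18. In this direction 5 unnamed or provisional clones were passed over.

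**Figure D1:**
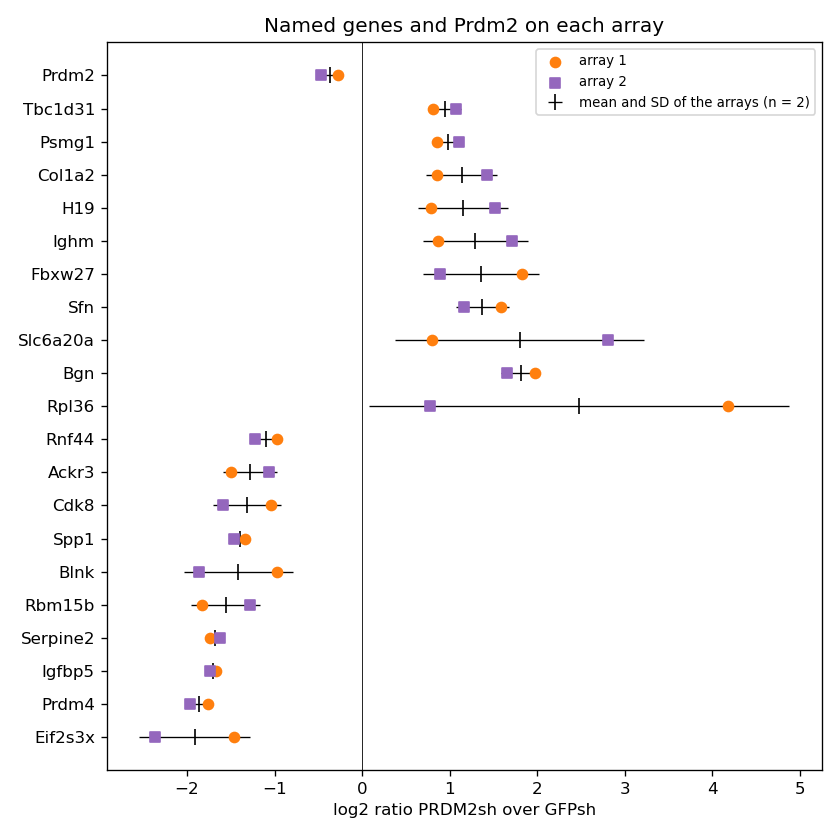
Log2 ratios of PRDM2sh over GFPsh (horizontal axis) for Prdm2 and the 20 genes with the highest and lowest values on both arrays. Circles are array 1, squares array 2, and bars the mean and SD (n = 2). Igfbp5, at -1.67 and -1.74, and Bgn, at 1.97 and 1.66, lie far from 0 on both arrays, while the Rpl36 values of 4.18 and 0.78 lie far apart.

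Several of these genes were measured by more than 1 clone. For Col1a2 both clones had mean log2 ratios close to each other, at 1.13 and 1.14. The arrays differed more, with 0.51 on array 1 and 1.74 on array 2 for the first and 0.85 and 1.42 for the second. For H19, 4 of 5 clones above the limit were positive on both arrays, and the other had -0.79 on array 1 and 2.42 on array 2. All 3 clones of Rrm2, a subunit of the ribonucleotide reductase that supplies DNA synthesis, were positive on both arrays, with means of 0.83, 0.86 and 0.34. Cyclin A2 (Ccna2) had 3 clones with means of 0.02, -0.96 and -0.26, and no clone had one sign on both arrays. Over the 813 named genes with at least 2 such clones, 14 were higher with every clone on both arrays and 25 lower. Shuffling clones among genes gave medians of 9 and 16 (one-sided permutation p = 0.076 and 0.014, not adjusted for the 2 directions).

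**Figure D2:**
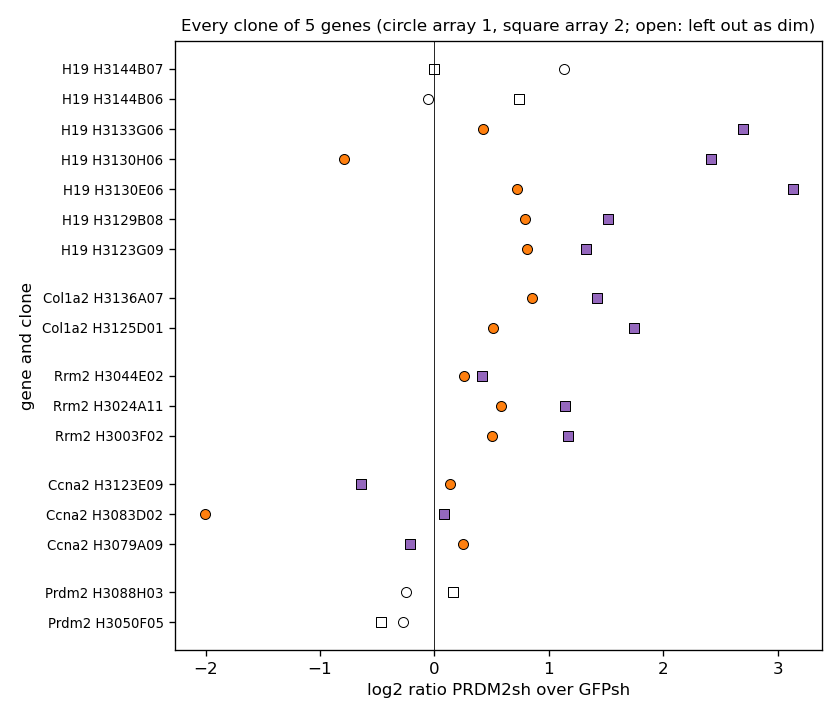
Log2 ratios of PRDM2sh over GFPsh (horizontal axis) for every clone of Prdm2, Ccna2, Rrm2, Col1a2 and H19 (vertical axis). Circles are array 1, squares array 2, and open symbols mark clones left out as dim. The 3 Rrm2 clones and both Col1a2 clones lie above 0 on both arrays, and the clones of Ccna2 lie on both sides.

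The arrays were then set against each other, since a transcript that follows the sample keeps its sign after the swapped array is turned and one that follows the dye changes it. Across the 6877 genes and clones the turned log2 ratios ran opposite, with Pearson r = -0.62 and Spearman rho = -0.62. These are correlations across genes, which are not independent replicates. Only 1830 (26.6%) had one sign on both arrays. At 1.5-fold on both arrays 59 were higher and 93 lower in PRDM2sh, against 1893 in opposite directions. At 2-fold these counts were 6, 13 and 828. The part that changed sign with the dye had an SD of 0.91 across genes, against 0.44 for the mean of both orientations. The direction rests on the dyes that the labels and the file headers both give. With array 2 not turned, 71 would be higher and 510 lower in the channel that held PRDM2sh on array 1.

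**Figure D3:**
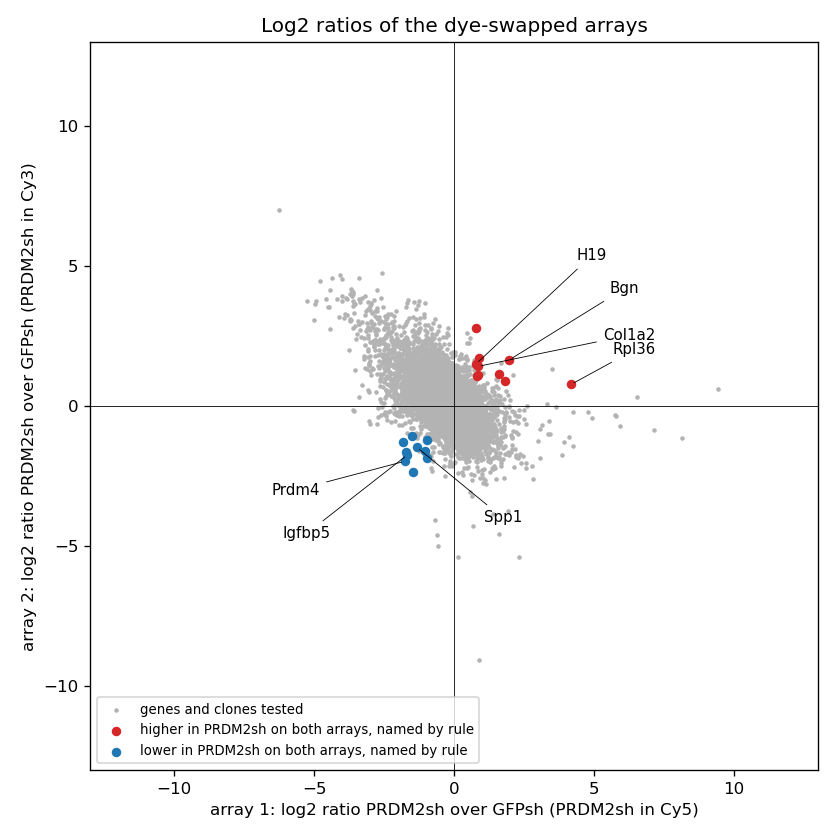
Log2 ratio of PRDM2sh over GFPsh on array 1 (horizontal axis) and array 2 (vertical axis), each point a gene or unnamed clone. Coloured points are the 10 highest and the 10 lowest named genes. The cloud slopes downwards (r = -0.62). The coloured points were picked for one sign on both arrays, so they lie in the upper right and lower left quadrants. Rpl36, at 4.18 and 0.78, and Slc6a20a, at 0.79 and 2.81, lie away from the other diagonal.

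Gene groups fixed in advance were compared next. None of the 14 lists tested passed camera, and none did with an estimated correlation (adjusted p of at least 0.92). The estimated form rests on 1 residual degree of freedom, so almost no list could pass with it. Its p values therefore weigh neither for nor against a list. In the gene test 0 members of any list passed, over all genes or adjusted over the list alone. The list test was tried on simulated data only without a dye component. Its power with the observed dye component is unknown, so a list that did not pass may still have changed. Of 17 measured genes of DNA replication, 4 were positive and 1 negative on both arrays. Rrm2 had a mean log2 ratio of 0.86 ± 0.40 and its partner subunit Rrm1 had 0.69 ± 0.11 (SD, n = 2; adjusted p of the list 0.61). Of 21 mitotic genes 2 were positive and 2 negative on both arrays (adjusted p = 0.46). Aurkb had 0.81 ± 1.86 and Cdca8 had -0.69 ± 0.55. Of 5 CDK inhibitors and growth arrest genes 2 were positive on both arrays, among them Foxo1 with 0.43 ± 0.09, and Ccng1 had -0.38 ± 0.17 (adjusted p = 0.61). Their median of 0.38 (0.10 on array 1, 0.49 on array 2, and -0.07 with no filter on dim clones) lay at the 97.6 percentile of random lists, and that of the other 12 lists, ribosomal proteins apart, between 31.2 and 94.5.

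Of 12 genes of the extracellular matrix and the TGF-beta response, 5 were positive and 3 negative on both arrays. Their median log2 ratio was 0.11 (adjusted p = 0.19), with medians of 0.40 on array 1 and -0.06 on array 2. Besides Bgn and Col1a2, the collagen gene Col5a1 had 0.79 ± 0.23 and Sparc had 0.54 ± 0.84. Without Bgn and Col1a2 the adjusted p of this list in camera was 0.94. These 2 were left out for their high values, so a larger p was bound to follow. The list passed camera where both channels had to be above the limit on both arrays (adjusted p = 0.0044). Over the alternatives the adjusted p ranged from there to 0.92. With an estimated correlation, which could hardly pass any list, the adjusted p under that filter was 0.76. Of 5 imprinted growth genes 2 were positive on both arrays, H19 and Mest, the latter with 0.46 ± 0.17 (adjusted p = 0.23). Of 63 ribosomal protein genes 10 were positive and 6 negative on both arrays, with a median of 0.06 (adjusted p = 0.11) and medians of -0.19 on array 1 and 0.33 on array 2. Rps25 had 9.44 on array 1, where both Cy3 spots were listed at 0, and 0.61 on array 2. The median lay at the 99.8 percentile of 10000 random lists of the same size and intensity, and at 99.5 without Rps25 and Rpl36, where it was 0.06. With median centring it turned to -0.11. Without Rps25 and Rpl36, also genes of high values, the adjusted p of this list in camera was 0.45, and a larger p was again bound to follow. The list passed camera with the mean over clones (adjusted p = 0.040) and with the authors' log2 ratios (adjusted p = 0.029). Over the alternatives the adjusted p ranged from 0.029 to 0.92. With an estimated correlation, which could hardly pass any list, the 2 passing settings had adjusted p = 0.91 and 0.94. Among 51 genes of oxidative phosphorylation 7 were positive and 5 negative (adjusted p = 1.00), and Cox7b, not well above background in PRDM2sh cells on either array, had a measured mean of -1.21 ± 0.63.

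Neither list of chromatin genes passed. Of 11 Polycomb genes 3 were positive and 2 negative on both arrays (adjusted p = 0.89). Their median log2 ratio was -0.002, with medians of 0.16 on array 1 and 0.61 on array 2. Rbbp4 had 0.55 ± 0.09 in its brightest clone and a mean of -0.15 in another, and Aebp2 had -1.39 ± 1.46, while the methyltransferase gene Ezh2 had 0.70 on array 1 and -1.19 on array 2. Of 14 genes of H3K9 methylation and heterochromatin 2 were positive and 4 negative (adjusted p = 0.46), with Ehmt1 at 0.65 ± 0.28 and Hdac2 at -0.65 ± 0.61 (0.01 in a dimmer clone). The median of this list was -0.10, with -0.16 on array 1 and -0.002 on array 2. The other adjusted p values were 0.46 for cholesterol synthesis (Lss, 0.80 ± 0.67, not well above background in GFPsh cells on either array), 0.75 for the interferon response (Irf1, 0.36 ± 0.44), 0.79 for Wnt and BMP signalling (Smad1, -0.43 ± 0.08), 1.00 for unfolded protein stress (Calr, 0.39 ± 0.47) and 0.61 for apoptosis regulators.

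Muscle genes were few. Myod1, Myog, Ccnd1 and Cdkn1a had 0 clones under these symbols. Of 3 measured myogenic regulators, Tcf3 had a mean log2 ratio of -0.53 ± 0.20 (0.20 in a dimmer clone), Id1 had 0.21 ± 1.11 and Id3 had -0.07 ± 0.17. Of 4 contractile genes the tropomyosin gene Tpm1 had 0.87 ± 0.67 and Mylpf had -0.34 ± 0.32. Another Tpm1 clone had -0.41 on array 1 and 1.81 on array 2. The other contractile genes changed sign between arrays 1 and 2, Tnnt1 with -0.57 and 2.00 and Tpm2 with -0.20 and 1.25. Of 4 muscle stem cell and Notch genes Sdc3 had -0.30 ± 0.21, and the other 3 had opposite signs on the arrays. The PRDM family had 2 measured members, Prdm4 and Prdm15, the latter with 0.11 ± 0.46. Of 2 measured histone genes H4c18 had 0.93 ± 1.05. Markers of other cell types were also few. The 4 blood and endothelial genes had opposite signs on the arrays, as did the only adipocyte gene (Lpl) and the only neuronal gene (Tubb3), and the only bone gene was Spp1. Lists with fewer than 5 measured members were not tested. Of the list members named, Foxo1, Ehmt1, Irf1, Prdm15, Aebp2, Ezh2, Lpl and Rps25 were above the limit in GFPsh on 1 of 2 arrays, and Cdca8, Smad1, Ezh2 and Lpl in PRDM2sh on 1 of 2.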

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

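The test in this part was chosen after the result was seen. Spots of Arabidopsis control DNA, which carry no mouse sequence and take part in no comparison, gave Cy3 signal above that of buffer spots. Their median Cy3 intensity was 994 on array 1 and 818 on array 2, against 309.6 and 324 for buffer. In Cy5 the medians were 26.7 and 38.5, against 23.7 and 69.1 for buffer. Most Arabidopsis spots were under the detection limit in each channel. Their Cy5 over Cy3 log ratios, which should hold no information on mouse RNA, went together between the arrays with r = 0.24 over 480 spots (one-sided permutation test, with the smallest p that 100000 shuffles can give). No biological explanation was tested for this signal.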

How the results depend on the processing

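The limit from Arabidopsis spots, clone spots within 2-fold, the left-out block, array 2 not turned and the removal of spots at 0 beside a bright channel were chosen after the data were seen. The count of genes at an adjusted p under 0.05 was 0 in both directions under all alternatives run except 2. With both channels above the limit on both arrays, 1 unnamed clone was lower, with log2 ratios of -0.57 and -4.99. With array 2 not turned, 71 were higher and 510 lower, the concordant and opposite counts became 1893 and 152, the correlation between arrays 0.62 and the Prdm2 log2 ratio 0.10. The 152 concordant genes at 1.5-fold became 262 with median centring (4369 opposite), 395 with no filter on dim clones, 53 with both channels above the limit (490 opposite), 83 with the limit from Arabidopsis spots (1253 opposite), 90 with clone spots within 2-fold, and 19 at 2-fold. The correlation was -0.79 with median centring and -0.48 with no filter. No list passed except under 3 alternatives with 1 list each. Extracellular matrix genes passed with both channels above the limit (adjusted p = 0.0044), and ribosomal proteins passed with the mean over clones (0.040) and with the authors' table (0.029). With an estimated correlation in camera the adjusted p was 0.76, 0.91 and 0.94 in that order. That form has 1 residual degree of freedom and could hardly pass any list, so it does not weigh against these calls. The cause was not tested for these changes beyond the number of clones each filter leaves. Leaving out spots at 0 beside a channel above its limit left 6353 genes and clones, 0 calls and 140 concordant genes. Prdm2 ranged from -0.47 to -0.27 on single arrays, and from -0.59 with the authors' table to -0.21 with the mean over clones among the other alternatives, array 2 not turned apart. Single arrays give no test and no count on both arrays. Of the 20 genes named for the highest or lowest values, 18 kept their sign under each alternative that gave them a value, array 2 not turned apart. These were 11 to 16 of 16 alternatives, and Slc6a20a, with 11, had no value where spots at 0 were left out or in the authors' table. Rpl36 and Fbxw27 did not keep their sign. A kept sign is weak support, since the 20 genes were picked for one sign on both arrays. Several alternatives, such as another filter or prior, can also leave a ratio unchanged. Bgn stayed at 1.81 with no filter on dim clones and with the trended robust prior. With array 2 not turned 13 of the 20 changed sign. The foreground-only alternative was not run, since 1 intensity is given per channel. The log ratio within each array already pairs the samples, and the separate-channel fit without that pairing gave 0 calls in both directions. Signal over background limits dim genes most, Prdm2 among them.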

Other observations

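The tests in this part were chosen after the results were seen, apart from the correlation between the arrays, which was fixed before the data were examined along with most of its settings. Genes measured by several clones and not yet described included the RNA helicase gene Ddx3x, with a mean log2 ratio over 2 clones of -0.92, and the DNA polymerase subunit gene Pole4, with -0.91. The lysosomal protease gene Ctsl had -0.62 over 2 clones that were both negative on both arrays. Gnai2 had 0.60 over 3 clones, with a smallest value of 0.003 for a clone on a single array. These genes were singled out after their values were seen, and none passed the test over all genes.

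The opposite ratios of the arrays may come from dye effects tied to spot or clone. The Cy5 over Cy3 ratio went together between arrays over Arabidopsis spots (r = 0.24), which carry no mouse sequence. Of these spots 4.8% on array 1 and 6.5% on array 2 were above the Cy5 limit, and 14.0% and 39.6% above the Cy3 limit. Most were thus near background, so this is weak support for dye effects on the clones kept. A background shared by position was not tested. For bright genes the dye part also went together between 2 clones of a gene (r = 0.40 over 207 pairs), which argues against the single spot as the whole cause there and leaves a dye effect that clones of one gene share open. The normalization as the whole cause is argued against by the correlation, which was at most -0.48 over every setting with array 2 turned. With the authors' log2 ratios in place of those used here the correlation was -0.53 over 6319 genes and clones. Taken as deposited over single spots, the authors' values correlated at -0.33. That value is not collapsed to genes and is not like for like with the others. A wrong dye label on 1 array cannot be told apart from dye effects for clones above the limit in all 4 channels (r = 0.52 over 4180), since both give a shared ratio there and Prdm2 was too dim to check the labels; a difference between the replicates also stays open, untested.

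Whether the mean of both orientations is noise of single clones was tested on the 2 brightest clones of each gene. All genes with such clones entered, not only those of one sign on both arrays. Over 207 pairs with log2 intensity above 11 the mean of both orientations went together (r = 0.37, permutation test). The part that changed sign with the dye did so about as well (r = 0.40). The value for the mean argues against clone noise as its whole cause over the bright genes as a set. Genes of one sign on both arrays, 26.6% of all genes and clones tested, were not tested on their own. H19 and Col1a2, picked for their values, are among these pairs, so r is no separate support for them. Over 606 dimmer pairs r for the mean of both orientations was 0.00015 (one-sided permutation p = 0.499), so values of dim genes may be noise. For bright genes an effect of the hairpin and a wrong dye label, under which the mean would hold a difference between replicates, both stay open. So does a dye effect of unequal size on the arrays, which would not cancel in the mean and was not tested.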
